A study of Rattus norvegicus with 20 samples.

How the data were processed

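Gene expression in the spinal dorsal horn of single Sprague-Dawley rats was measured on 20 two-colour cDNA arrays, 5 arrays in each of 4 groups. Electroacupuncture (EA), electrical stimulation through acupuncture needles, had been given for 30 min at 2 Hz or at 100 Hz, and tissue was taken 24 h later from the lumbar segments L5 and L6. Within each frequency the submitters called rats high responders (HR) or low responders (LR) by how strongly EA reduced their response to pain. This gives the groups 2Hz-HR, 2Hz-LR, 100Hz-HR and 100Hz-LR. For the 100Hz-LR group, 1 label field gives the abbreviation of the other class, and the group was taken from the remaining fields. On every array the rat's RNA carried Cy3, and a single mix of RNA from 5 rats that had not received EA carried Cy5. No dye was swapped.

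Per the labels, RNA was purified on columns, reverse transcribed and labelled. The labels describe both direct labelling with Superscript II and a T7 amplification kit, so which was used stays open. Per the file headers, spot images were quantified with ImaGene 5.1, while the labels name version 4.2. The deposited scanner files hold the intensity of each spot and of its local background in each channel, on a linear scale and without background subtraction or normalization per the file headers. Each array holds 12288 spots in 48 sub-grids of 256. The authors' table of processed values, also deposited, lists 11712 of these positions with a signed score per array whose unit no header or label gives. The 576 positions it leaves out were treated as controls or blanks. The score rose with the Cy3 to Cy5 ratio of the scanner files. Its column medians in replicate order were -0.00206, 0.00504, 0.0225, 0.00989 and -0.000276 for 2Hz-HR. They were -0.00746, -0.00206, 0.0165, -0.00809 and 0.000423 for 2Hz-LR. They were 0.00427, -0.0116, 0.00818, 0.0106 and -0.00187 for 100Hz-HR. They were -0.00172, -0.00929, -0.00748, 0.0166 and 0.0215 for 100Hz-LR. Its log base, the method of centring and its scaling stayed unknown. It served as an alternative only.

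In the files used here a spot is identified by its grid position alone and is not paired with a gene name. The 34 gene lists and cell type marker lists fixed before the data were examined, and the rule for naming genes fixed with them, could therefore not be applied, and no gene is named. The 2 highest and 2 lowest spots named by position were chosen after their values were seen. They have the largest mean log2 ratio in each direction among spots past the threshold against the control pool in all 4 groups, above background on all 20 arrays and not saturated.

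Starting from the deposited intensities, the background was corrected with the normexp method and an offset of 50, and log2(Cy3/Cy5) was normalized within each array by global loess with control positions at weight 0. Spots with flag code 1 (0 to 564 per array) were left out, and those with flag code 2 (798 to 2534 per array) were kept. Spots were tested where the mean signal lay over 2 background SDs above the local background in at least 1 channel on at least 5 arrays, which 11147 spots met. The offset draws the ratios of dim spots towards 0, and loess sets the typical ratio of each array to 0, so a shift shared by most genes would not be seen. The 4 group means were fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the spots tested and a threshold of 0.05. Differences between groups cancel the dye and the pool. A group against the pool is tested as its mean ratio against 0: the pool counts as 1 control sample, the spread between control rats is left out, and any dye bias of a spot stays in the value. Each array is a separate rat, so the p-values measure the spread between rats together with that between arrays.

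The alternatives were other background corrections and normalizations, other filters on dim spots, the median spot signal, the deposited score, blocks for replicate number, slide and date, other arrays in the fit, other moderation and weights, a minimum fold of 1.5, and each array left out in turn. Blocks were read from the slide numbers and from dates in the headers. Scanning fell into 4 sessions and slides into 6 runs of neighbouring numbers. Random blocks used statmod 1.5.0. The fit was tested on simulated arrays with the residual SD of each real spot and independent noise, with 200 spots shifted at once by a known amount. The SD of a spot was the same in all groups. In real groups whose arrays vary more, recovery would be lower than simulated. Fewer true shifts would be harder to recover after adjustment, so the recovery does not hold for changes in a few spots. Comparisons of whole profiles used permutation tests on the 8608 spots measured on all arrays. Figures were drawn with matplotlib 3.10.9.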

Results

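Ratios to the control pool were obtained for 11147 spots in dorsal horn of 20 rats, 5 in each group. Between 84.4% and 92.9% of the positions analysed lay above background in at least 1 channel of an array. The median Cy3 signal was 656 ± 150 intensity units (SD, n = 5) in 2Hz-HR, 573 ± 179 in 2Hz-LR, 530 ± 162 in 100Hz-HR and 341 ± 90.3 in 100Hz-LR. The groups were also scanned apart. Session 1 held 4 of the 2Hz-HR arrays, and session 2 held 1 array each of 2Hz-HR and 2Hz-LR. The 4 arrays of session 1 also made up a separate slide series, and the other 16 came from another. Session 3 held 4 arrays each of 2Hz-LR and 100Hz-HR with 1 of 100Hz-LR, and session 4 held 1 array of 100Hz-HR and 4 of 100Hz-LR. In exact two-sided permutation tests of 4 array measures over the 4 pairs of groups (16 tests), the lowest unadjusted p was 0.00794, for the share of spots above background in 2Hz-HR (91.6% ± 0.590, SD, n = 5) against 100Hz-HR (87.6% ± 2.21). It is the smallest p that 5 against 5 can give, and the adjusted p was 0.127.

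**Figure D1:**
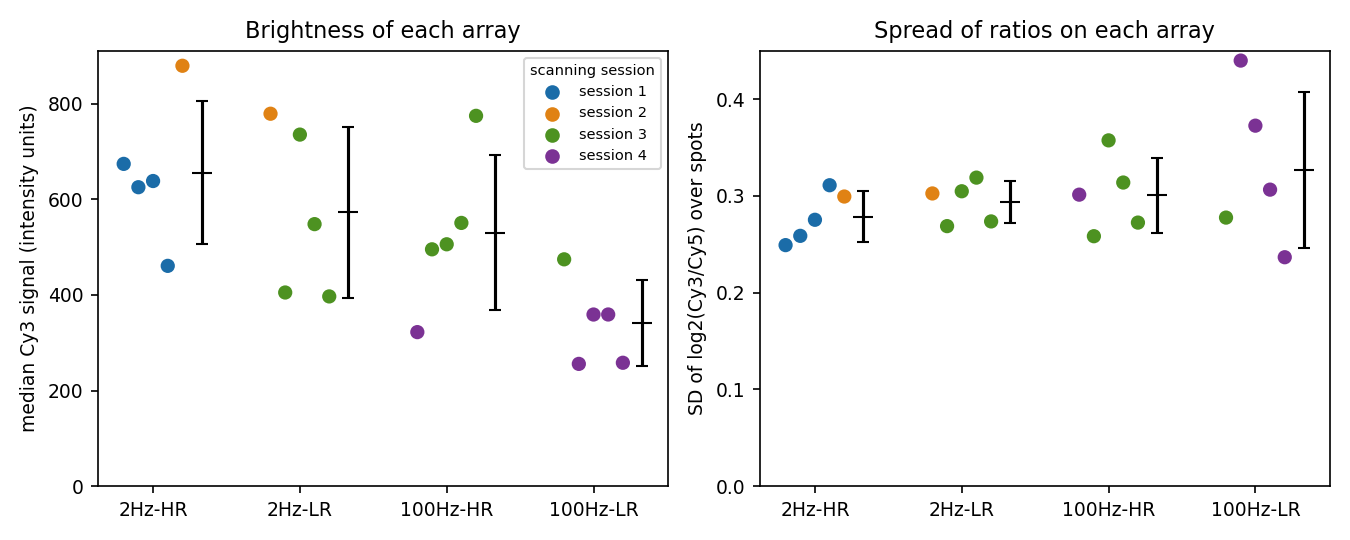
Median Cy3 signal in intensity units (left) and SD of log2(Cy3/Cy5) over spots (right) for each of the 20 arrays, coloured by scanning session, with the group mean and SD (n = 5) as black bars. The 4 arrays of 100Hz-LR in session 4 lie between 256 and 359 intensity units, and the SD of the ratios reaches 0.44 on 100Hz-LR replicate 2.

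The first comparison asked which transcripts differ between rats that respond strongly and weakly to 2 Hz EA. The spot with the smallest p was higher in 2Hz-HR, with a log2 ratio to the pool of 0.24 ± 0.12 (SD, n = 5) against -0.29 ± 0.16 in 2Hz-LR. The difference of 0.54 (SE 0.094) is 1.45-fold, and its adjusted p in limma was 0.130. The spot with the smallest p in the other direction stood at 0.0057 ± 0.074 in 2Hz-HR and at 0.36 ± 0.09 in 2Hz-LR, a difference of -0.35 (SE 0.074, adjusted p in limma 0.402). This spot was dim, above background on 9 of 20 arrays, where the offset draws ratios towards 0. No spot passed the threshold in limma (0 of 11147). At an unadjusted p under 0.05 there were 810 spots, 491 higher and 319 lower in 2Hz-HR, where 5% would be 557. With slide runs as a random block the unadjusted count was 520, on the deposited scores 688, and in a fit of these 10 arrays alone 1234. Such a fit leaves the differences as they are and changes only the spread they are held against. Group means differed by at least 1.5-fold for 45 spots, none of which passed. The 95% interval of a spot's difference was typically ± 0.23 on the log2 scale. In simulated arrays the same fit recovered 2, 155 and 194 of 200 spots shifted by 0.3, 0.6 and 1 on that scale. With the scanning session as a block 9 spots passed, of 10532 that could be tested, and the difference then rests on 1 rat of each group, those of session 2. Within that session 1 array faces 1, which allows no test.

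For 100 Hz EA, the bright spot with the smallest p was higher in high than in low responders. Its log2 ratio was -0.17 ± 0.13 (SD, n = 5) in 100Hz-HR and -0.56 ± 0.066 in 100Hz-LR, a difference of 0.40 (SE 0.075), or 1.32-fold, with an adjusted p in limma of 0.287. In the other direction the leading spot differed by -0.36 (SE 0.079, adjusted p in limma 0.317), at -0.49 ± 0.13 in 100Hz-HR and -0.13 ± 0.12 in 100Hz-LR. Again 0 of 11147 spots passed in limma, and 827 had an unadjusted p under 0.05, of which 351 were higher and 476 lower in 100Hz-HR. A fit of these 10 arrays alone gave 439 and the deposited scores 472, both below the 557 that 5% would be, so the excess depends on the setting. Other splits of the same 10 arrays gave a median of 772 in the main setting, little below the 827. Means differed by at least 1.5-fold for 28 spots. The fit recovered 1, 159 and 197 of 200 simulated spots shifted by 0.3, 0.6 and 1. Sessions 3 and 4 each held both groups. Each within-session fit had a lone array in 1 group, which was assumed to vary like the others. In session 3, 4 rats of 100Hz-HR against 1 of 100Hz-LR gave 0 spots past the threshold and 303 of 11060 at an unadjusted p under 0.05. In session 4, 1 rat of 100Hz-HR against 4 of 100Hz-LR gave 18 past the threshold and 501 of 10963 at an unadjusted p under 0.05. Across 10883 spots, which are not independent replicates, the differences of the 2 sessions had a Pearson r of 0.103 and a Spearman's rho of -0.000152. With the session as a block 0 spots passed.

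The frequencies were then compared among high responders. The leading spot was higher after 2 Hz, at 0.16 ± 0.20 (SD, n = 5) in 2Hz-HR and -0.43 ± 0.12 in 100Hz-HR, a difference of 0.59 (SE 0.11) or 1.51-fold with an adjusted p in limma of 0.121. A bright spot led in the other direction, at -0.074 ± 0.12 against 0.29 ± 0.077, a difference of -0.36 (SE 0.087, adjusted p in limma 0.638). No spot passed in limma (0 of 11147), and 642 had an unadjusted p under 0.05, 382 of them higher and 260 lower in 2Hz-HR. With slide runs as a random block the unadjusted count was 424, on the deposited scores 625, and in a fit of these 10 arrays alone 952. The means of 43 spots differed by at least 1.5-fold. Of 200 simulated spots, 16, 156 and 191 were recovered at shifts of 0.3, 0.6 and 1. No scanning session held both groups. With the session as a block, which links them only through the other groups, 7 spots passed.

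Among low responders, the leading spot after 2 Hz stood at 0.27 ± 0.19 (SD, n = 5) in 2Hz-LR and at -0.16 ± 0.17 in 100Hz-LR, a difference of 0.43 (SE 0.090) or 1.35-fold with an adjusted p in limma of 0.272. The leading spot in the other direction stood at -0.50 ± 0.16 and -0.090 ± 0.096, a difference of -0.41 (SE 0.080) with the same adjusted p in limma of 0.272. None of the 11147 spots passed in limma (0), and 1131 had an unadjusted p under 0.05, which was 10.1% of those tested, 527 higher and 604 lower in 2Hz-LR. A fit of these 10 arrays alone gave 708 and the deposited scores 567. At least 1.5-fold separated the means of 37 spots. The fit recovered 10, 159 and 192 of 200 simulated spots at shifts of 0.3, 0.6 and 1. Without 100Hz-LR replicate 1, the array of that group scanned in session 3, 26 spots passed. The 2 groups then shared no session, so frequency and session could not be told apart. Within session 3, 4 rats of 2Hz-LR against 1 of 100Hz-LR gave 0 spots past the threshold and 313 of 11064 at an unadjusted p under 0.05. The lone array was assumed to vary like the others, and it came from another slide run than the 4 rats of 2Hz-LR. The comparison within session 3 thus sets no firm check on the 26 spots. With the session as a block 0 spots passed.

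Whether the difference between responder classes itself depended on frequency was tested as an interaction. The leading spot with a positive interaction (HR minus LR at 2 Hz, less HR minus LR at 100 Hz) gave 0.70 (SE 0.15, adjusted p in limma 0.356), with group means of 0.044 ± 0.097 (SD, n = 5) in 2Hz-HR, -0.25 ± 0.14 in 2Hz-LR, -0.25 ± 0.15 in 100Hz-HR and 0.15 ± 0.22 in 100Hz-LR. The difference between the classes thus had opposite signs at the 2 frequencies, which picking the spot by its interaction favours. The leading spot in the other direction gave -0.53 (SE 0.11, adjusted p in limma 0.356). It was the same dim spot that had the smallest p among those lower in 2Hz-HR than in 2Hz-LR. There were 0 spots past the threshold in limma and 969 at an unadjusted p under 0.05, or 513 on the deposited scores. The interval of a spot's interaction was typically ± 0.33, and 0, 100 and 164 of 200 simulated spots were recovered at shifts of 0.3, 0.6 and 1. Without 100Hz-LR replicate 1, 8 spots passed, and 8 passed with the session as a block.

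**Figure D2:**
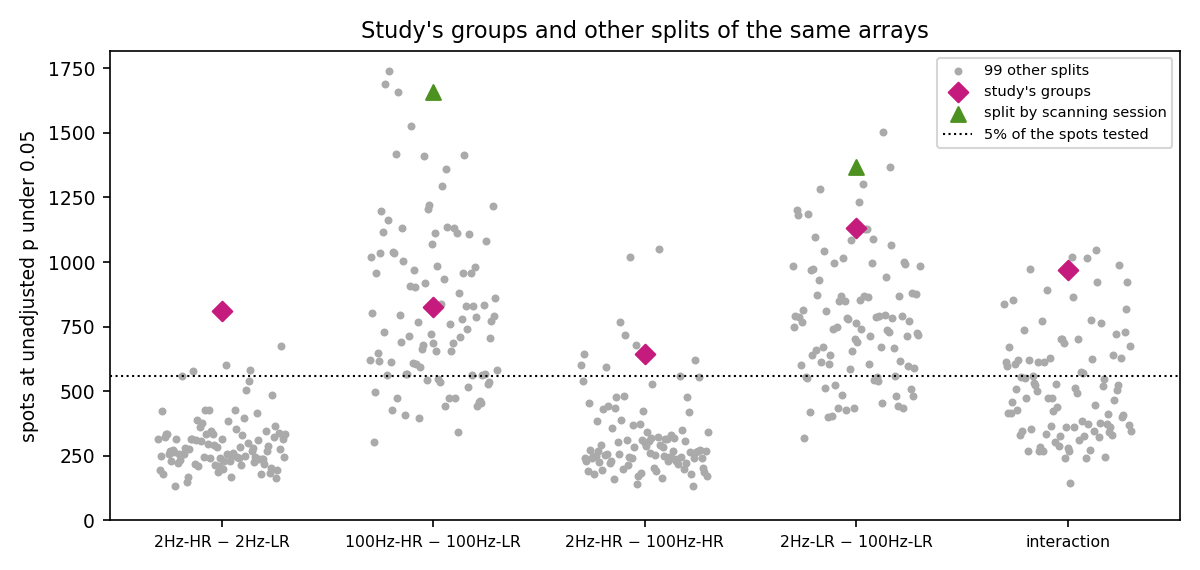
Spots at an unadjusted p under 0.05 (vertical axis) for the study's groups (diamonds), for 99 other splits of the same arrays (grey points) and, for 2 comparisons, for the split of the 10 arrays by scanning session (triangles), with a dotted line at 5% of the spots tested. The study's groups give 810 spots between the responder classes at 2 Hz, and the split by session gives 1660 among the 100 Hz arrays, where the study's groups give 827.

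Whole profiles were also compared, by permutation tests chosen after the data were examined (4 tests, 100000 permutations each). The 4 groups took up 19.2% of the variation between arrays (permutation p = 0.0304, adjusted p = 0.0405) and the 4 scanning sessions 21.3% (p = 0.0258, adjusted p = 0.0405). Any split of the arrays into 4 classes takes up part of the variation by chance, so most of such a share need not be an effect. Permuted within sessions, the groups gave a permutation p = 0.673 (adjusted p = 0.673). This test can say little on 2Hz-HR, since 4 of its arrays made up session 1 and could not change label. Permuted within groups, the sessions gave a permutation p = 0.0207 (adjusted p = 0.0405). Between pairs of groups, in exact tests over all 126 splits, 2Hz-HR and 2Hz-LR were further apart than under any other split (p = 0.00794, adjusted p over 4 tests = 0.0317). These groups share only session 2, with 1 array each, and 4 of the 2Hz-HR arrays came from the separate slide series. The exact p was 0.0556 for 2Hz-HR against 100Hz-HR (adjusted 0.111), 0.143 for 2Hz-LR against 100Hz-LR (adjusted 0.190) and 0.389 for 100Hz-HR against 100Hz-LR (adjusted 0.389).

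Against the pool of unstimulated rats, many spots differed in every group, mostly by small amounts. In limma, 1774 spots were higher and 1300 lower in 2Hz-HR, 2073 higher and 1815 lower in 2Hz-LR, 1985 higher and 1757 lower in 100Hz-HR, and 1674 higher and 1670 lower in 100Hz-LR. The median size of these ratios lay between 0.30 and 0.32 on the log2 scale, and 275, 102, 126 and 227 of the spots reached 1.5-fold in the same order of groups. In all 4 groups alike, 884 spots were higher and 488 lower. Independent lists of these lengths would share 8.82 and 5.0, and simulated groups without any effect that share a pool of 5 rats gave means of 0.2 and 0.7. The group means correlated across spots with a mean r of 0.781 over the 6 pairs of groups, where the same simulation gave 0.495. Their mean covariance was 0.0423, and the simulated one 0.00953. Part of the excess may come from the shared pool, which is 1 sample and could not be split. The simulation also held no dye bias of single spots, which all 4 groups would share. The excess over it is therefore no measure of a response to EA alone. With the session as a block the calls came to 17, 730, 254 and 160 in the 4 groups, and the deposited scores gave 9, 28, 1 and 10. The session block tests each group's mean set at an average over the sessions, including those that held none of its arrays. Its calls are thus not a like count to those of the main setting. Group means of the deposited scores correlated with a mean r of 0.312.

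The spot with the largest mean ratio, Sr07Sc02R02C14, was higher than the pool in all 20 rats. Its log2 ratio was 1.15 ± 0.22 (SD, n = 5) in 2Hz-HR, 1.28 ± 0.31 in 2Hz-LR, 1.33 ± 0.24 in 100Hz-HR and 1.32 ± 0.25 in 100Hz-LR, or 2.22- to 2.52-fold, with adjusted p in limma between 3.17e-07 and 1.63e-06. Sr10Sc01R04C02 followed with 1.29 ± 0.42, 1.21 ± 0.24, 1.29 ± 0.36 and 1.11 ± 0.43 in the same order. The lowest, Sr03Sc03R02C05, a bright spot, stood at -1.15 ± 0.21, -1.06 ± 0.71, -1.21 ± 0.15 and -1.30 ± 0.47. It lay below the pool in 19 of 20 rats. Sr07Sc03R03C15 was lower in all 20 rats, at -0.66 ± 0.18, -0.73 ± 0.16, -0.78 ± 0.24 and -1.05 ± 0.79. The first 2 did not pass in every group on the deposited scores or with the quantification day as a block. The other 2 also did not with the session as a block or without the 4 arrays of the separate slide series. These blocks set each group at an average over all sessions or days. The mean ratios over the groups then stayed mostly as large while the SE rose. Single groups moved more, such as Sr10Sc01R04C02 with the day block, at 0.66 in the lowest group and 1.5 in the highest. Over the 4 groups the mean ratios in this order were 1.27, 1.22, -1.18 and -0.81 in the main setting, with an SE of 0.11, 0.15, 0.18 and 0.17 in each group. With the day block they were 1.28, 1.01, -1.21 and -0.83, with SE of at least 0.20, 0.23, 0.31 and 0.29, and with the session block the last 2 were -1.29 and -0.82, with SE of at least 0.27 and 0.25. Without the separate slide series the last 2 were -1.12 and -0.78. The deposited scores, in an unstated unit, averaged 1.43, 0.68, -1.35 and -1.05, with SE of 0.34, 0.49, 0.32 and 0.55.

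**Figure D3:**
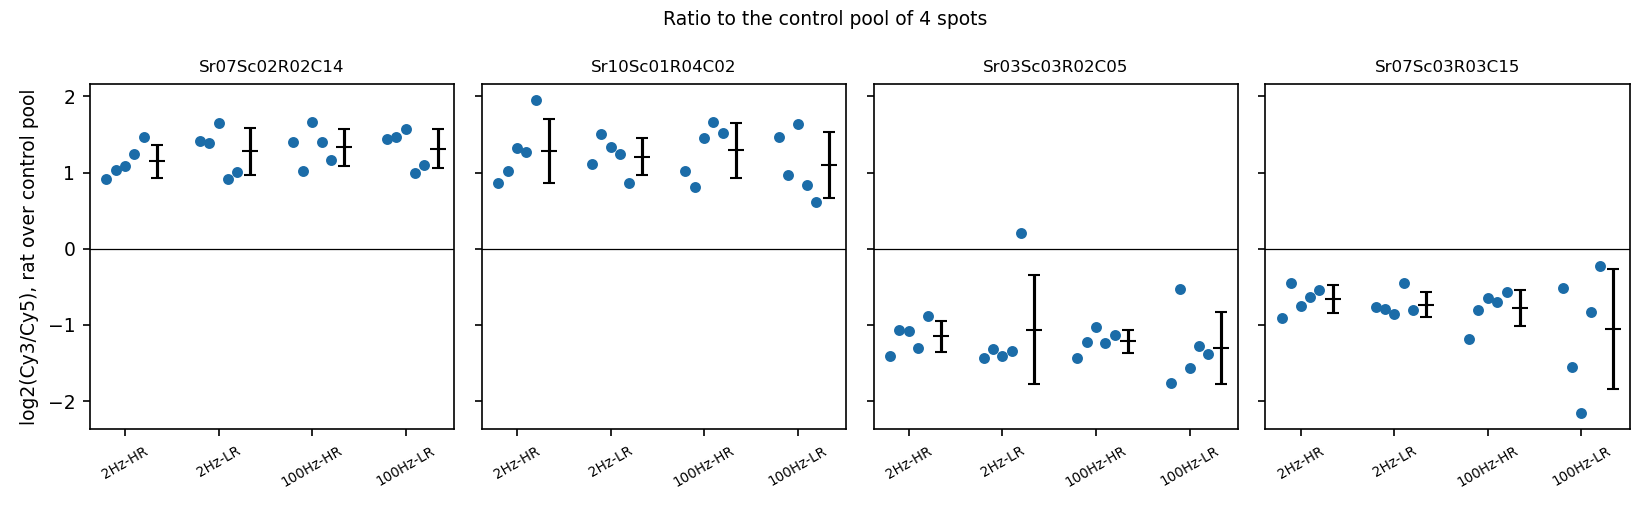
Log2(Cy3/Cy5), rat over control pool, of 4 spots in each rat (blue points, 5 per group), with the group mean and SD as black bars. The first 2 spots lie above 0 and the last below 0 in all 20 rats, while Sr03Sc03R02C05 is above 0 in 1 rat of 2Hz-LR, at 0.21.

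**Figure D4:**
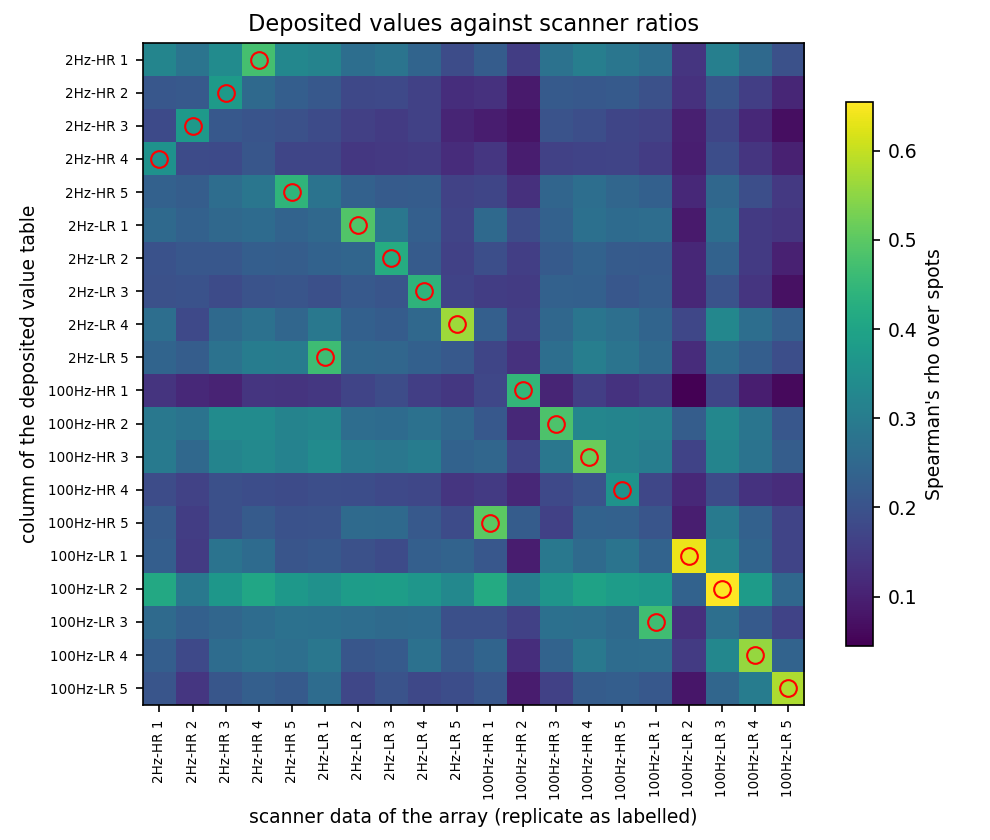
Spearman's rho over spots between each column of the authors' deposited value table (rows) and the scanner ratio of each array (columns), with the highest of each row circled. In all 20 rows the circle lies in the same group, and in 3 rows it lies on the array of the same replicate.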

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

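The samples were screened for single values far from the rest of their group, over 36 groups of 5 values; 3 stood out, where chance gives about 1 in 20 groups, or 1.8 here. The 4 spots screened were themselves chosen after their values were seen. Spot Sr03Sc03R02C05 stood at a log2 ratio of 0.21 in 2Hz-LR replicate 5, while the other 4 rats of the group lay between -1.44 and -1.32. The same array had a mean correlation of 0.391 with all other arrays, below the 0.500 to 0.542 of the rest of its group. Spot Sr07Sc03R03C15 stood at -0.45 in 2Hz-LR replicate 4, with the other 4 rats between -0.85 and -0.76. Among the positions that the deposited table leaves out, 45 of the 48 at row 1 and column 1 of each sub-grid lay above background in both channels on all 20 arrays, with a median Cy3 signal of 7228 intensity units.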

How the results depend on the processing

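Between groups, 0 spots passed in the main setting and in most alternatives. With the replicate number as a block 0 spots passed in all 5 between-group comparisons. Same-numbered arrays of different groups did not deviate together (mean r of -0.0112 over 30 pairs, and 2 of 20 arrays correlated best with their own number), so the numbers of the scanner data gave no sign of pairing. The deposited table matched another order, so this does not show that rats were unpaired. For 2Hz-HR minus 2Hz-LR, plain background subtraction gave 1 spot, only the slide series with all 4 groups 6, the scanning session as a block 9, the quantification day as a block 11 and array weights 5. For 2Hz-HR minus 100Hz-HR, scaling between arrays gave 2, the slide series 7, the session block 7, the day block 6 and array weights 24. For the interaction, the slide series gave 4, the session block 8 and the day block 7. The day block gave 1 spot each for 100Hz-HR minus 100Hz-LR and for 2Hz-LR minus 100Hz-LR. Under the slide series and the session and day blocks listed here, the comparisons of 2Hz-HR are carried by 1 array of that group. Leaving out each array in turn gave 0 to 1 for 2Hz-HR minus 2Hz-LR (1 without 2Hz-LR replicate 1), 0 to 0 for 100Hz-HR minus 100Hz-LR, 0 to 1 for 2Hz-HR minus 100Hz-HR (1 without 2Hz-HR replicate 5), 0 to 26 for 2Hz-LR minus 100Hz-LR and 0 to 8 for the interaction.

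Against the pool, the counts of 3074, 3888, 3742 and 3344 spots (2Hz-HR, 2Hz-LR, 100Hz-HR, 100Hz-LR) stayed within 1.5 times under the other background, normalization, filter and signal settings tried on the scanner data, and under random blocks. The session block gave 17, 730, 254 and 160, the day block 3, 158, 166 and 490, a minimum fold of 1.5 gave 275, 102, 126 and 227 (84.0%, 68.6%, 90.5% and 47.1% of them higher, against 57.7%, 53.3%, 53.0% and 50.1%), and the deposited scores 9, 28, 1 and 10, of which 8, 26, 1 and 9 were lower. For 2Hz-HR, the slide series gave 17, its own arrays alone 4980 and array weights 5453; for 100Hz-LR, its own arrays alone gave 1297. Fits of a group's own arrays leave its mean ratios as they are, so their counts changed through the spread and the arrays behind it. Array weights, larger where arrays vary less, were 1.35 to 2.41 in 2Hz-HR and 0.18 to 1.09 in 100Hz-LR. The spread shared by all groups in the main setting may thus be too wide for 2Hz-HR and too narrow for 100Hz-LR. Otherwise the cause was not tested, except that the session and day blocks and the slide series leave fewer arrays to each estimate. These 2 blocks also test another quantity, the group mean set at an average over all sessions or days, including those without the group. Leaving out each array gave 2166 to 3706, 2918 to 4464, 2526 to 4299 and 2328 to 3427. The 4 spots named by position kept their direction throughout. The session as a random block was chosen after seeing the data (consensus correlation -0.00745). The gene list alternatives were not run, since spots are not paired with genes. Spots too dim for the filter were not tested in the main setting.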

Other observations

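The regroupings of spots past the adjusted threshold for the 4 pairs of groups and the interaction, the tests of the deposited table, and the correlations of group means were chosen after the results were seen. The others below were set before their own result was seen, but after the main comparisons.

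High against low responders over both frequencies, 10 rats against 10, gave 0 spots past the threshold in limma and 573 at an unadjusted p under 0.05, with a typical 95% interval of ± 0.17 on the log2 scale. Of 100 regroupings within each frequency, 31 gave as many spots at an unadjusted p under 0.05 and the highest other gave 973. 2 Hz against 100 Hz over both classes gave 0 past the threshold and 753 at an unadjusted p under 0.05. Of 100 regroupings within each class 17 gave as many, and the highest other gave 1369. Past the adjusted threshold any regrouping reaches a real count of 0 (100 of 100 in both, with highest others of 1 and 0), so these regroupings decide nothing. With the scanning session as a block 5 and 1 spots passed.

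In the main setting, more than 5% of spots had an unadjusted p under 0.05 in each of the 4 pairs of groups and the interaction. That line of 557 spots is nominal, and other splits of the same arrays lay on both sides of it. Their median was 274 spots for 2Hz-HR minus 2Hz-LR, 772 for 100Hz-HR minus 100Hz-LR and 269 for 2Hz-HR minus 100Hz-HR. It was 762 for 2Hz-LR minus 100Hz-LR and 500 for the interaction. The share above 5% also depends on the setting. With slide runs as a random block the share was 4.67% for 2Hz-HR minus 2Hz-LR, 5.53% for 100Hz-HR minus 100Hz-LR, 3.8% for 2Hz-HR minus 100Hz-HR, 7.44% for 2Hz-LR minus 100Hz-LR and 5.88% for the interaction. With the scanning session as a block it was 2.37%, 3.32%, 2.25%, 3.53% and 2.61% in the same order. With the session as a random block it was above the main setting in all 5, at 7.66%, 7.85%, 6.04%, 10.8% and 9.2%, and array weights gave 1444 spots for 2Hz-HR minus 2Hz-LR. A fit of the compared arrays alone, which changes only the spread the differences are held against, gave 1234, 439, 952 and 708 spots (11.07%, 3.94%, 8.54% and 6.35%) for the 4 pairs. On the deposited scores little excess was left, with 6.18%, 4.24%, 5.61%, 5.09% and 4.61%. Past the adjusted threshold the real count was 0, which any regrouping reaches (100 of 100 each), so these regroupings decide nothing. The highest others were 1 for 2Hz-HR minus 2Hz-LR, 231 for 100Hz-HR minus 100Hz-LR, 0 for 2Hz-HR minus 100Hz-HR, 1 for 2Hz-LR minus 100Hz-LR and 1 for the interaction. At an unadjusted p under 0.05, the share of regroupings with as many spots was under 0.05 only for 2Hz-HR minus 2Hz-LR, where the real split alone, 1 of 100, reached 810 spots and the highest other gave 673. Chance is thus unlikely for that count taken alone, but it is not excluded. The rank is the most extreme of several regrouping tests and was not adjusted for them. The test was not repeated in other settings, such as slide runs as a block, where the count was 520. As many spots came up in 45 of 100 for 100Hz-HR minus 100Hz-LR (827, highest other 1738), 7 for 2Hz-HR minus 100Hz-HR (642, highest other 1052), 9 for 2Hz-LR minus 100Hz-LR (1131, highest other 1502) and 6 for the interaction (969, highest other 1047). Chance cannot be excluded for these 4 either. The split of the 100 Hz arrays with 231 spots past the threshold had 3 arrays of session 4 and 2 of session 3 on 1 side, so it did not follow the session, and what sets it apart was not tested.

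A candidate explanation for these spots is the scanning session. Split 5 against 5 by session, the 10 arrays of the 100 Hz groups gave 1660 spots at an unadjusted p under 0.05 and 48 past the threshold, against 827 and 0 for the study's groups. These counts are from the main setting, and the excess of the 827 was absent in the fit of the compared arrays alone (439) and on the deposited scores (472). The other drawn splits of these arrays had a median of 772 spots, little below the 827. The session split is what the session explanation needs, though 2 other drawn splits gave still more spots at an unadjusted p under 0.05, and hybridisation and handling may have gone with the session. The session as a random block gave a consensus correlation within sessions of -0.00745. The counts did not fall, at 875 spots for 100Hz-HR minus 100Hz-LR and 1200 for 2Hz-LR minus 100Hz-LR. This fit can say little on the session, since it also fits the group means and most arrays of each group shared a session. Slide runs as a random block gave a consensus correlation within runs of 0.0788. The counts then fell to 616 for 100Hz-HR minus 100Hz-LR and 829 for 2Hz-LR minus 100Hz-LR. Slide runs thus stay open as well, and no split by slide run was tested. In the permutation test of whole profiles, the sessions permuted within groups gave p = 0.0207 (adjusted p = 0.0405). That test covered the arrays of all groups, not the 100 Hz arrays alone. The session thus stays open for the 100 Hz groups. The low responder arrays lie in 3 sessions. Session 3 against sessions 2 and 4 together gave 1369 spots against 1131 for the study's groups, which leaves the session open there. For 2Hz-HR minus 2Hz-LR, exchanging the groups of the 2 arrays of session 2 gave 578 spots, 253 of them among the 810 of the study's groups. Session and responder class cannot be told apart, because no other session holds both groups. The 4 arrays of 2Hz-HR in session 1 also made up the separate slide series. The slide series thus goes with the session here and cannot be told apart from responder class either. The most deviating array, 100Hz-LR replicate 2, does not account for the low responder comparison in the main setting, since 9.13% of spots had an unadjusted p under 0.05 without it. It stays open for 100Hz-HR minus 100Hz-LR (6.94%). The responder class itself stays open as well for the comparisons between classes, and the stimulation frequency for the low responder comparison.

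The ratio profile shared by the 4 groups, with a mean correlation of 0.781 between group means, could come from a response to EA common to all rats, from the difference of the pool from the mean of control rats, or from a dye bias of single spots. It was weaker in the deposited scores, where group means correlated with a mean r of 0.312 (0.252 to 0.363), and single arrays with 0.0897 against 0.482 for the scanner ratios of the same spots. The cause of this was not tested, since the processing behind the scores is not stated in full. A simulated pool of 5 rats without any effect gave a mean covariance of 0.00953 against 0.0423 observed, which sets no bound, since the spread between control rats was not measured here. The content of the bright positions outside the deposited table is not stated. Their median log2 ratio on each array averaged -0.11 ± 0.10 (SD over 20 arrays) and lay below 0 on 17 arrays. Ratios of single positions among them were not examined. The 3 explanations cannot be told apart, because no array carries an unstimulated rat in Cy3 and no dye was swapped.

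The columns of the authors' deposited value table did not follow the replicate numbers of the scanner data. Only 3 of 20 columns ranked highest with the array of the same sample, with a Spearman's rho of 0.355 to 0.654 over spots for the highest array and 0.116 to 0.580 for the array of the same sample. A candidate explanation is that columns were filled in ascending slide number within each group, since all 20 columns ranked highest with the array at that place. An exchange of arrays between groups is argued against, as 0 columns ranked highest with an array of another group. Differences between group means do not depend on this order, while any pairing of replicates between both sources would. No biological explanation was tested.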
